A study of Mus musculus with 10 samples.

How the data were processed

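RNA from the hearts of 10 male mice, 5 S1Pless and 5 control, was analysed. Per the labels' protocols, total RNA was isolated with TRIzol and RNeasy columns and libraries were built with a stranded mRNA kit from Illumina. The values are raw read counts per Ensembl gene, as the authors deposited them in 1 table for all samples. STAR 2.7.8a, featureCounts 2.0.1 and the genome build GRCm39 are named per the submitters' processing notes. The annotation release, the strand setting, the treatment of reads that map to several places and the rule that selected the genes in the table are not given in the sources used here. Counts of genes in families of near-identical copies, such as Ccl21a, Serpina3g, the MHC genes and the haemoglobin genes, are therefore uncertain, as are those of overlapping genes.

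The table held 15341 genes, of which 347 had a count of 0 in all libraries, and no column was left unused. Ensembl identifiers were matched to symbols with the gene name table of GENCODE M21; 20 had no symbol and 6 shared one with another gene. The reference annotation is of an older build than the counts, so no coordinates are given. Samples were assigned to groups by genotype as the labels state it, and replicates were numbered in accession order. Each heart is a separate sample in the labels, and the labels pair no animal with another. The number that ends each column name runs through all controls before all S1Pless hearts, so library order follows group. No pair of libraries of the same group agreed within sampling noise (chi-square per degree of freedom of 10.5 or more in all 20 pairs).

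The groups were compared with edgeR 4.0.16 in R 4.3.3 on the counts: filterByExpr with a minimum count of 10, TMM factors, glmQLFit with robust estimation and glmQLFTest, two-sided, with Benjamini-Hochberg adjustment over the 12992 genes tested and a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of the F statistic. CPM values are scaled by the TMM factors, which were 0.955 ± 0.0478 in controls and 1.05 ± 0.0328 in S1Pless hearts (exact permutation p = 0.0159, adjusted p = 0.0952 over 6 library measures). The biological coefficient of variation was 15.2%, and the median log2 fold change of all tested genes was -0.01. Library measures, such as depth and the share of mitochondrial transcripts, were compared with two-sided exact permutation tests over the arrangements of the 10 hearts, with Benjamini-Hochberg adjustment.

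Before the data were examined, 48 gene lists of cell types and pathways were fixed, of which 43 had at least 3 tested members. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists, and beside it with an estimated correlation and with fry. With the preset correlation 10 lists were higher and 10 lower. With an estimated correlation none passed (lowest adjusted p = 0.334, 4 lists below an unadjusted p of 0.05), and none passed in fry's directional test (lowest adjusted p = 0.0502, 16 lists below an unadjusted p of 0.05). A list's score in a library is the mean log2 CPM of its tested members.

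The genes named in the text follow a rule fixed before the data were examined: the kinase genes Sphk1 and Sphk2, among called genes with a mean of at least 1 CPM and a named symbol the 10 largest rises and 10 largest falls and the 5 smallest p-values in each direction, up to 4 called members of each list described or, where none was called, up to 2 with the smallest p-values, and the S1P receptors with Nppa, Nppb, Myh7, Myh6 and Acta1. Of the genes this rule picks, 1 is not described. The genes named outside this rule were chosen after their values were seen: Prox1 as the exception in its list, Gapdh, Slc15a2 and Cxcl13 for their spread, and the members of an added list of NF-kappaB targets.

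The test was tried on simulated counts for the same 12992 genes with 5 libraries against 5. It recovered 58.9% of genes changed 1.5-fold, 83.6% of those changed 2-fold and 99.1% of those changed 4-fold, with 4.36% false calls among all calls, and called the planted list and 0 of 40 unchanged lists. Each gene was drawn independently, and the simulated hearts shared no structure beside their groups. The simulation therefore cannot test lists of correlated genes or likeness between hearts. In the real data the estimated correlation was 0.565 in the macrophage list and 0.703 in the oxidative phosphorylation list. Depth limits what low genes can show: Sphk1, with 8 to 27 reads per library, carried a standard error of 0.28 on the log2 scale.

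Alternatives fixed before the data were examined were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom with quality weights, no filter, a filter of 1 CPM in 5 libraries, removal of haemoglobin and mitochondrial genes, a covariate for the series of the number in the sample title, and leaving out each heart. Added after seeing the data were a fit without the library of lowest quality weight in each group, 2 blocks for neighbouring title numbers, a covariate for the first residual component, one for the haemoglobin share, and library totals alone in place of TMM factors. Hearts fell into separate levels of the block where their title numbers lay at least 100 apart from the next, or at least 50 for the narrower block.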

Results

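Gene expression was measured by RNA sequencing in the hearts of 10 male mice, 5 plasma S1Pless animals and 5 littermate controls. Sphingosine 1-phosphate (S1P) is a lipid messenger formed by the sphingosine kinases, which Sphk1 and Sphk2 encode, and it acts on blood vessels, heart muscle and immune cells through the receptors S1pr1 to S1pr5. Both groups carried floxed over null alleles of both kinase genes. The S1Pless animals also carried Mx1-Cre, a recombinase under an interferon-inducible promoter that is active in blood-forming cells. The comparison asks how the heart's transcripts differ in animals described as lacking plasma S1P. It does not isolate plasma S1P, since cells of the heart in which Mx1-Cre acts may lose the kinases themselves. The libraries held 17204491 to 20202283 counts in controls and 16354071 to 20832566 in S1Pless hearts. No difference in depth between the groups was found (two-sided exact permutation p = 0.540). Levels are given as CPM, a gene's count scaled to a common library total, and a single count was worth 0.0451 to 0.0658 CPM, depending on the library.

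The targeted kinase genes showed no call in whole heart RNA. Sphk1 (ENSMUSG00000061878) had 1.21 ± 0.36 CPM in controls and 0.723 ± 0.21 CPM in S1Pless hearts (SD, n = 5 each), from 16 to 27 reads per control library and 8 to 18 per S1Pless library, a log2 fold change of -0.74 ± 0.28 (SE). Sphk2 (ENSMUSG00000057342) had 20.2 ± 2.3 and 16.8 ± 1.9 CPM, a log2 fold change of -0.27 ± 0.11. Neither passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.168 for Sphk1 and 0.180 for Sphk2). Both were lower in S1Pless hearts, with unadjusted p-values of 0.0208 and 0.0241 in that test. The groups overlapped in both genes. Counts over a whole gene do not separate the floxed from the null allele, and Mx1-Cre acts in blood-forming and some other cells, so these values check the labels only in part. Among the other genes of S1P synthesis, breakdown and transport, Ugcg, which encodes glucosylceramide synthase, rose 1.40-fold (adjusted p = 0.0273) and was the only 1 of 22 tested members past the threshold, both over all genes and adjusted over the list alone. All 5 S1Pless hearts lay above all controls, and the call was lost without control replicate 2, 3 or 4 or S1Pless replicate 5 (adjusted p up to 0.0729, without control replicate 3). The list as a whole had a median log2 fold change of 0.01, opposite in sign to the direction of limma's camera test (adjusted p = 0.906). None of the 5 S1P receptor genes passed. Their log2 fold changes were 0.12 ± 0.15 for S1pr1, 0.11 ± 0.13 for S1pr2, 0.14 ± 0.11 for S1pr3, 0.36 ± 0.23 for S1pr4 and -0.35 ± 0.36 for S1pr5. The edgeR adjusted p-values ran from 0.417 to 0.700, and camera gave an adjusted p of 0.448 for the receptors as a list.

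Far more genes were higher than lower in S1Pless hearts. Of 12992 genes tested, 442 were higher and 41 lower at an adjusted p below 0.05 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and of these 138 were higher and 4 lower by more than 2-fold. Ubd (ENSMUSG00000035186), which encodes the cytokine-inducible ubiquitin-like protein FAT10, had the largest rise of all called genes, from 0.422 ± 0.22 to 5.53 ± 2.3 CPM (13.1-fold, adjusted p = 0.000535). Col28a1 (ENSMUSG00000068794), a collagen gene, rose 4.93-fold from 1.48 ± 0.49 to 7.25 ± 1.4 CPM. Kit (ENSMUSG00000005672), the stem cell factor receptor, rose 2.66-fold from 4.96 ± 0.71 to 13.2 ± 2.0 CPM, Lrrc36 (ENSMUSG00000054320) 2.63-fold and Ccdc88c (ENSMUSG00000021182), a regulator of Wnt signalling, 2.08-fold from 18.8 ± 2.7 to 39.2 ± 4.3 CPM. These 4 genes had the same adjusted p of 0.000535. In all 5 of these genes each S1Pless heart lay above the highest control. Among called genes with a mean of at least 1 CPM and a symbol that is not a predicted or clone name the next largest rises were in Slamf8 (3.64-fold), Adgre4 (3.42-fold), F2rl3, the thrombin receptor PAR4 (3.42-fold), Plac8 (3.31-fold), the interferon-induced antiviral gene Mx1 (3.29-fold), Serpina3g (3.27-fold), the complement gene C6 (3.18-fold) and Rad51ap1 (3.17-fold), with edgeR adjusted p-values from 0.0143 to 0.0397. The groups overlapped in Serpina3g and C6 and not in the others. Without control replicate 3 or 4 the calls of Slamf8, F2rl3, Plac8, Serpina3g and C6 were lost. Some of them were also lost without control replicate 2 or 5 or S1Pless replicate 1, 3 or 5 (adjusted p up to 0.109, Plac8 without control replicate 3). Mx1 lost its call without control replicate 4 (adjusted p = 0.0508). Plac8 and Serpina3g did not pass with limma-voom or the title series covariate, nor C6 with limma-voom (adjusted p of 0.0503 to 0.0712).

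Among the genes that fell, Med16 (ENSMUSG00000013833), a subunit of the Mediator complex, dropped 2.11-fold from 34.5 ± 6.6 to 16.4 ± 2.4 CPM (edgeR adjusted p = 0.00371), with every S1Pless heart below the lowest control. Ighd, the constant region of the B cell antibody IgD, fell 3.00-fold from 1.56 ± 0.405 to 0.514 ± 0.167 CPM (adjusted p = 0.0136), and Slc1a1, a glutamate transporter gene, 1.74-fold (adjusted p = 0.0155). Paqr9 fell 1.41-fold from 61.7 ± 7.4 to 43.9 ± 2.9 CPM (adjusted p = 0.0177). Igsf23 fell 5.14-fold (adjusted p = 0.0430), although control replicate 1 had 0.987 CPM, within the S1Pless range of 0.858 to 3.89 CPM, and the other 4 controls had 8.77 to 11.9 CPM. Egln3, an oxygen-sensing prolyl hydroxylase, fell 1.68-fold, Hpdl 1.58-fold, Pdp2, a phosphatase that activates pyruvate dehydrogenase, 1.57-fold, Lingo3 1.55-fold, Adra1b, the alpha-1B adrenergic receptor, 1.55-fold and Gal3st3 1.5-fold (edgeR adjusted p from 0.0205 to 0.0487). The groups overlapped in Igsf23, Pdp2 and Adra1b. Igsf23 and Pdp2 each lost the call in 8 of 10 fits with a heart left out. Igsf23 kept it only without control replicate 1 or S1Pless replicate 5 and Pdp2 only without control replicate 1 or S1Pless replicate 3 (adjusted p up to 0.112 and 0.115). Every other gene of this paragraph except Med16, Ighd and Slc1a1 lost it without control replicate 3, 4 or both, and some also without other hearts, of which control replicate 1 was never one (adjusted p up to 0.0836, Hpdl without control replicate 3). With library totals alone Pdp2 and Paqr9 did not pass (adjusted p = 0.0832 and 0.0535). Igsf23 did not pass with limma-voom, no filter or the title series covariate, Pdp2 with neither other filter nor that covariate, and Hpdl not with that covariate (adjusted p of 0.0505 to 0.0754).

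**Figure D1:**
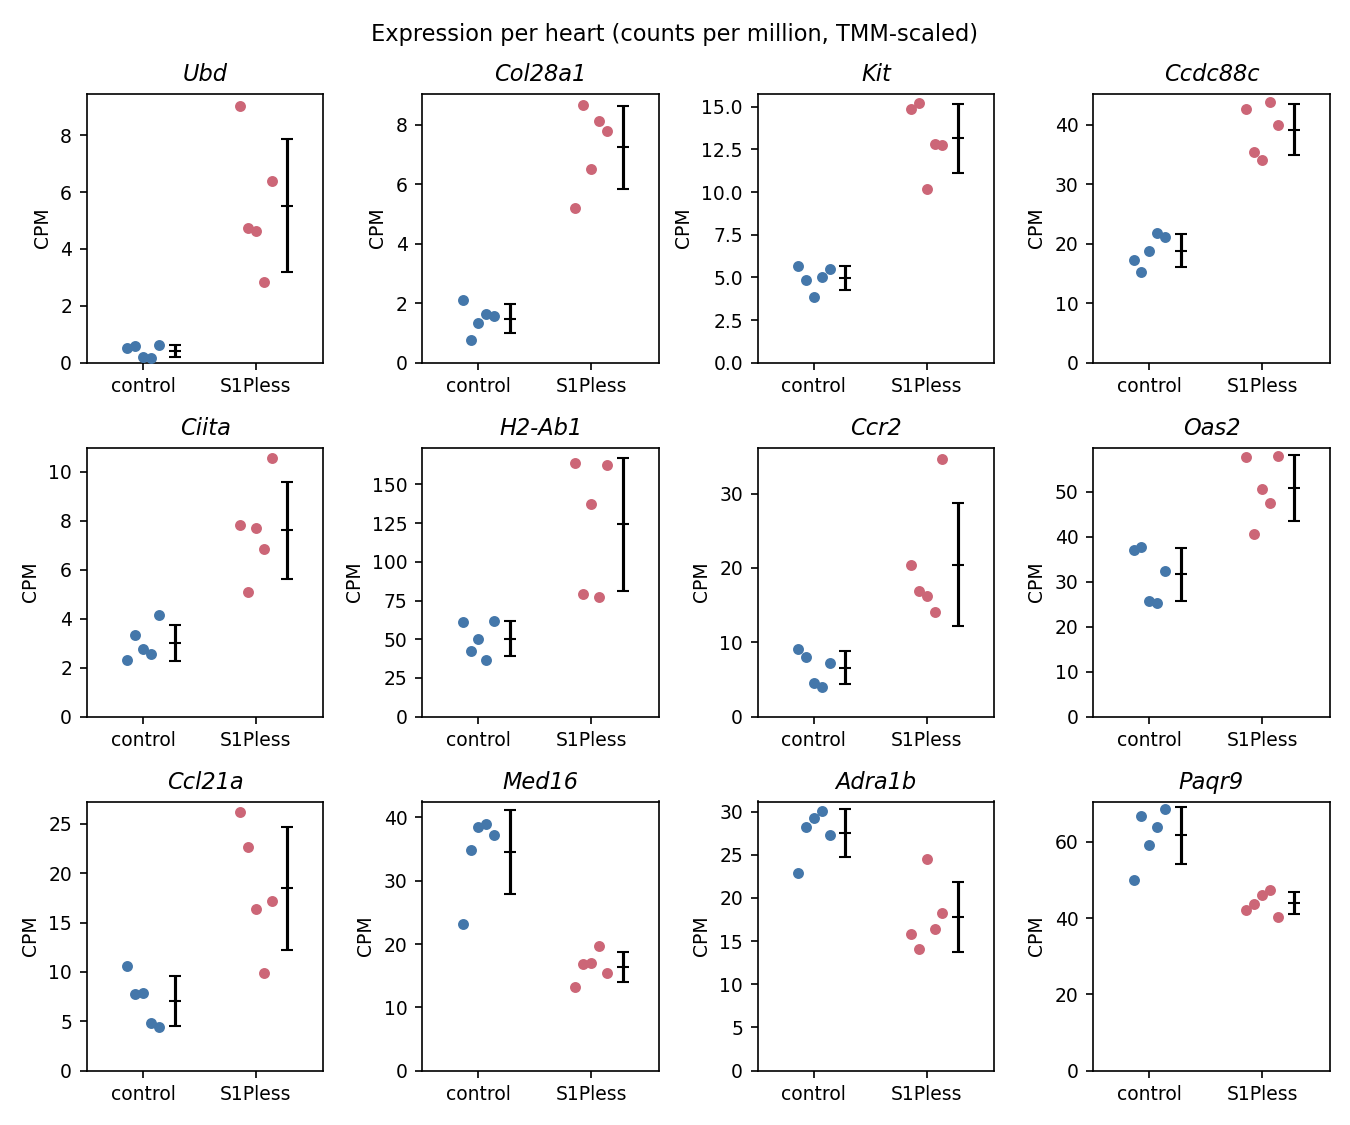
Expression of 12 genes in each heart, in CPM on linear axes that start at 0; each point is 1 heart, and the bar beside each group gives its mean and SD (n = 5). In Ubd, Col28a1, Kit, Ccdc88c, Ciita, H2-Ab1, Ccr2 and Oas2 all S1Pless hearts lie above all controls, in Med16 and Paqr9 all lie below them, and in Ccl21a and Adra1b the groups overlap.

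The number of calls moved with single libraries, while no called gene changed its sign. Non-overlapping groups were seen in 825 of the 12992 tested genes, against a share of 0.794% by chance. They were seen in 403 of the 483 called genes, but these were picked for a group difference in the same hearts. The chance share does not apply to them. Leaving out control replicates 2, 3, 4 or 5 left 278, 126, 131 and 237 calls, and leaving out S1Pless replicates 1 or 5 left 288 and 239. The 41 lower genes became 85, 17, 8, 9 and 14 without control replicates 1 to 5, and 19, 19 and 18 without S1Pless replicates 1, 4 and 5. DESeq2 called 753 genes higher and 266 lower. Ubd, Col28a1, Kit, Lrrc36, Ccdc88c, Adgre4, Rad51ap1, Med16, Ighd, Slc1a1, Ddx58, Ciita, H2-Ab1, Ccr2, Aif1, Traf1, Relb, Tnfaip3, Nfkbie, Tnf and Cd40 were the 21 of 64 called genes named here or below that passed in all 10 fits with a heart left out. Of the 64, 60, 41, 23, 24 and 41 passed without control replicates 1 to 5 and 43, 54, 56, 54 and 37 without S1Pless replicates 1 to 5. The title of each sample carries a number whose meaning is not stated, and a block for hearts with neighbouring numbers, chosen after seeing the data, left 22 calls (21 higher and 1 lower). Control replicates 3 and 4 shared a level of that block with no S1Pless heart, so they added nothing to the group difference. The fall in calls therefore cannot be laid to neighbouring numbers alone. With that block only Ubd, Col28a1, Kit, Lrrc36, Ccdc88c, Med16 and Cd40 of the 64 still passed. Of the 64, 55 passed with the series of the title number as a covariate and 59 in limma-voom. With a narrower block, in which control replicates 3 and 4 and S1Pless replicate 5 each stood alone, 16 of the 64 passed. With the haemoglobin share as a covariate 8 did. With library totals alone in place of TMM factors, also chosen after seeing the data, log2 fold changes shifted by a median of 0.136, with 1420 genes higher and 13 lower. Each fold change also compares animals with and without the recombinase itself, and libraries numbered later with libraries numbered earlier.

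On principal components of log2 CPM the first component, with 30.9% of the variance, separated the groups: controls lay between -23.6 and -3.77 and S1Pless hearts between 6.10 and 34.2, with S1Pless replicate 5 farthest out. The second component, with 22%, spread both groups alike, with control replicates 1 and 3 and S1Pless replicates 1 and 2 on its negative side.

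**Figure D2:**
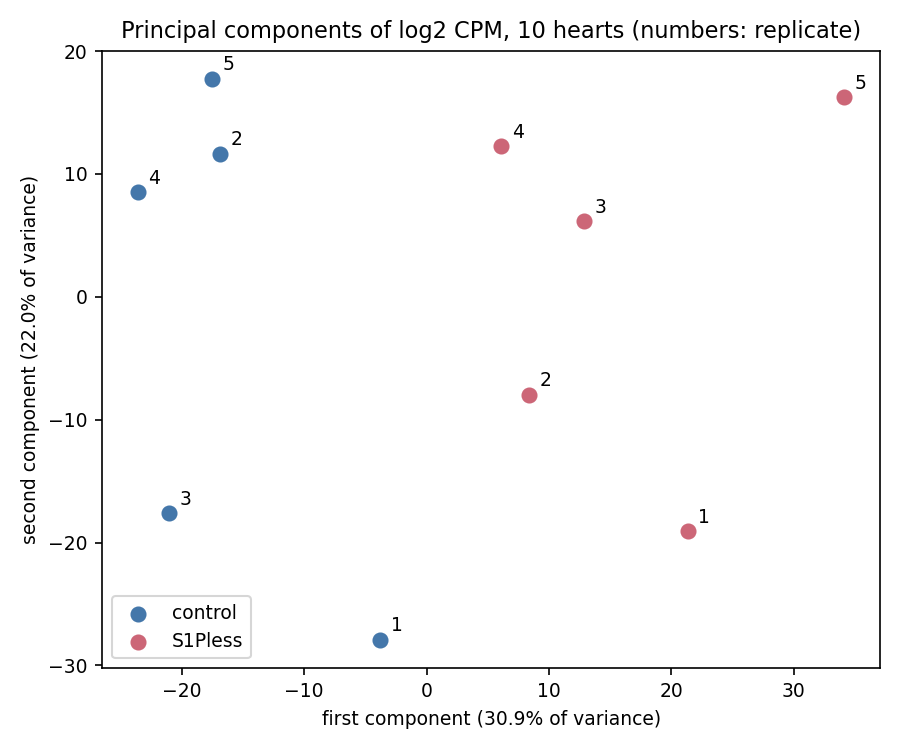
The 10 hearts on the first and second principal components of log2 CPM over the tested genes, with the share of variance on each axis; each point is 1 heart, coloured by group and numbered by replicate. The groups separate along the first component, and along the second each group spreads over positive and negative values.

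Markers of macrophages, genes of antigen presentation and interferon-induced genes were higher in S1Pless hearts. Of 20 macrophage markers, 9 were higher and none lower over all genes tested, all 20 were higher when adjusted over the list alone, and the median member was 1.80-fold higher. Ccr2, the receptor that brings monocytes into tissue, rose from 6.58 ± 2.2 to 20.4 ± 8.3 CPM (3.12-fold, edgeR adjusted p = 0.0119). Aif1, which encodes IBA1, rose 2.76-fold (adjusted p = 0.0177), Csf1r, the receptor for macrophage growth factor, 1.84-fold (adjusted p = 0.0255) and Tyrobp 1.78-fold (adjusted p = 0.0265). In the antigen presentation list 10 of 17 members were higher, 15 when adjusted over the list alone, with a median of 1.94-fold. Its examples were Ciita, the master regulator of MHC class II, at 2.51-fold (adjusted p = 0.00739) and Cd74, the invariant chain, at 2.37-fold (adjusted p = 0.0177). H2-Ab1 rose from 50.4 ± 11 to 124 ± 43 CPM (2.46-fold, adjusted p = 0.0139) and H2-Aa 2.40-fold (adjusted p = 0.0192). Of 29 genes of the type I interferon response 10 were higher and none lower, 23 were higher when adjusted over the list alone, and the median was 1.61-fold. Besides Mx1, this group held Ddx58, the viral RNA sensor RIG-I (1.54-fold, adjusted p = 0.0119), Xaf1 (1.6-fold, adjusted p = 0.0187) and Oas2, which makes the activator of RNase L (1.61-fold, adjusted p = 0.0192).

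Camera with its preset correlation called these 3 lists with adjusted p-values of 1.73e-12, 6.13e-12 and 1.73e-12 for the macrophage, antigen presentation and interferon lists. Each had an adjusted p = 0.334 with an estimated correlation. S1Pless replicate 5 had the highest macrophage score, a mean log2 CPM of 5.38 against 4.31 to 4.57 in the other S1Pless hearts and 3.64 to 3.98 in controls. Without control replicate 3 the calls of Cd74, H2-Aa, Xaf1, Oas2, Csf1r and Tyrobp were lost, and without control replicate 4 those of all of these but Cd74. Without control replicate 2 or 5 the calls were lost of Csf1r and Tyrobp, and without S1Pless replicate 1 that of Tyrobp (adjusted p up to 0.07, Csf1r without control replicate 4). The share of haemoglobin transcripts was 0.00738 ± 0.00331% in controls and 0.0118 ± 0.00393% in S1Pless hearts (exact permutation p = 0.0952, adjusted p = 0.222 over 6 library measures). With this share as a covariate, chosen after seeing the data, 20 genes passed the threshold, 19 higher and 1 lower, of which 18 and 1 were among the calls without it. The interferon score of S1Pless replicate 3, at 3.30, lay below the highest control score of 3.31.

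Markers of lymphatic vessels and genes of the extracellular matrix were also higher. Of 7 lymphatic endothelial markers 4 were higher. Ccl21a, the chemokine that guides dendritic cells into lymph vessels, rose from 7.09 ± 2.5 to 18.5 ± 6.2 CPM (2.62-fold, edgeR adjusted p = 0.0192). Mmrn1 rose 2.11-fold (adjusted p = 0.0303), Lyve1, which macrophages also express, 1.76-fold (adjusted p = 0.0306) and Reln 1.74-fold (adjusted p = 0.0180). Adjusted over the list alone, 5 were higher and 1 lower, the lower one being Prox1, the regulator of lymphatic identity, with a log2 fold change of -0.34 ± 0.15 and an adjusted p of 0.218 over all genes. In the list of matrix and fibrosis genes 3 of 32 were higher, 15 when adjusted over the list alone, with a median of 1.31-fold. S1Pless replicate 5 stood apart with a matrix score of 5.82 (mean log2 CPM), against 5.03 to 5.18 in the other S1Pless hearts and 4.74 to 5.07 in controls, and without it the median log2 fold change was 0.23 instead of 0.39. Col6a1 rose 1.36-fold (adjusted p = 0.0362), Fbn1, which encodes fibrillin, 1.47-fold (adjusted p = 0.0373) and Col4a1, a basement membrane collagen, 1.48-fold from 430 ± 71 to 636 ± 99.7 CPM (adjusted p = 0.0388). Camera called both lists (adjusted p = 0.00124 and 3.34e-07), with an adjusted p = 0.334 and 0.345 with an estimated correlation. Camera called both lists whichever heart was left out. Reln and Ccl21a lost their calls without control replicate 3 or 4. Mmrn1 lost its call without control replicates 2 to 5 or S1Pless replicate 1 or 5, and Lyve1 without control replicates 3 to 5 or S1Pless replicate 2 or 5 (adjusted p up to 0.0874, Lyve1 without control replicate 4). Col6a1 lost its call without control replicates 2 to 5 or S1Pless replicate 4 or 5. Fbn1 lost it in 8 of 10 fits (all but those without S1Pless replicate 1 or 2) and Col4a1 in 8 of 10 (all but those without control replicate 2 or S1Pless replicate 2). Their adjusted p-values ran up to 0.115, for Col4a1 without S1Pless replicate 5. Lyve1 and Col6a1 did not pass with the title series covariate (adjusted p = 0.0592 and 0.0571).

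Few general markers of vessel and stromal cells passed the threshold. Erg, an endothelial transcription factor, rose 1.31-fold (edgeR adjusted p = 0.0332) as the only 1 of 18 endothelial markers past the threshold, and the fibroblast marker Dpep1 rose 1.46-fold (adjusted p = 0.0454) as the only 1 of 12, each also when adjusted over its list alone. Both genes lost their calls without control replicates 2 to 5 or S1Pless replicate 1, 2 or 5, and Dpep1 also without S1Pless replicate 3 (adjusted p up to 0.119, Dpep1 without S1Pless replicate 5) and with RLE factors (adjusted p = 0.0542). Camera did not call the endothelial, fibroblast, smooth muscle or pericyte lists (adjusted p = 0.170, 0.0989, 0.171 and 0.136), whose median log2 fold changes were 0.15, 0.18, -0.16 and 0.14. Without control replicate 1 camera called the endothelial and fibroblast lists (adjusted p = 0.0456 and 0.0379), and without control replicate 4 the smooth muscle list (adjusted p = 0.00598). With the block of neighbouring title numbers it called the fibroblast and smooth muscle lists (adjusted p = 0.0141 and 0.00838), with the narrower block the smooth muscle list (adjusted p = 7.59e-05), and without the library of lowest quality weight in each group the fibroblast list (adjusted p = 0.0197). All of these use the preset correlation, and with all hearts and no covariate the endothelial, fibroblast and smooth muscle lists had an adjusted p = 0.657, 0.645 and 0.645 with an estimated correlation. Of 17 genes of endothelial activation and permeability, the leukocyte adhesion genes Icam1 (1.66-fold, adjusted p = 0.0177) and Vcam1 (1.55-fold, adjusted p = 0.0415) and the interferon-induced chemokine gene Cxcl9 (2.29-fold, adjusted p = 0.0433) were higher. Adjusted over the list alone 4 were higher, while camera gave the list an adjusted p of 0.0577. That list passed without control replicate 2 (adjusted p = 0.0275) or S1Pless replicate 4 (adjusted p = 0.00895), with RLE factors (adjusted p = 0.0463), with the series of the title number as a covariate (adjusted p = 0.0350) and with the haemoglobin share (adjusted p = 0.0138), each with the preset correlation. With all hearts and no covariate it had an adjusted p = 0.437 with an estimated correlation. Icam1 lost its call without control replicate 3 or 4, Vcam1 without control replicates 2 to 5 or S1Pless replicate 1, 2 or 5, and Cxcl9 without any control replicate or without S1Pless replicate 1, 2 or 5 (adjusted p up to 0.112, Cxcl9 without control replicate 3). Cxcl9 also lost it with limma-voom, no filter or the title series covariate (adjusted p of 0.0623 to 0.0806).

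Among 40 regulators and receptors of vascular tone 1 was higher and 1 lower. Nos2, the inducible nitric oxide synthase, rose from 17.2 ± 1.8 to 26.9 ± 5.2 CPM (1.57-fold, edgeR adjusted p = 0.0209), and Adra1b fell 1.55-fold from 27.5 ± 2.8 to 17.8 ± 4.0 CPM (adjusted p = 0.0228). Adjusted over the list alone 2 were higher and 1 was lower, and camera gave an adjusted p of 0.549 for the whole list. Neither gene passed without control replicate 3 or 4, Nos2 also not without S1Pless replicate 5, and Adra1b also not without control replicate 2 or S1Pless replicate 1 (adjusted p up to 0.0661, Adra1b without control replicate 4).

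Genes of heart muscle metabolism lay slightly below control levels as groups, with few single calls. All 39 tested nuclear-encoded genes of oxidative phosphorylation had negative log2 fold changes, with a median of -0.26, and none passed in edgeR without a covariate, over all genes or adjusted over the list alone. Sdhc had a log2 fold change of -0.30 ± 0.10 (edgeR adjusted p = 0.117) and Ndufs1 one of -0.26 ± 0.10 (adjusted p = 0.162). Both passed in DESeq2 (adjusted p = 0.0180 and 0.0238) and in edgeR with the first residual component as a covariate, chosen after seeing the data (adjusted p = 0.0126 and 0.0379). Of 27 genes of fatty acid oxidation 26 had negative values, with a median of -0.28. S1Pless replicate 3 went the other way, with a score of 8.33 above all controls (7.95 to 8.24), while the other S1Pless hearts had 7.58 to 7.71. Without it the median was -0.34. The oxidative phosphorylation scores of the groups overlapped, with 8.84 to 9.36 in controls and 8.62 to 8.99 in S1Pless hearts. Control replicates 1 and 3 had 9.36 and 9.35, while the other controls, at 8.84 to 8.90, lay below S1Pless replicates 1 and 2 at 8.99 and 8.97. The estimated correlation between the members of this list was 0.703, so their 39 negative values are not independent. Hadhb, a subunit of the mitochondrial trifunctional protein, fell 1.32-fold from 658 ± 53 to 498 ± 40 CPM (adjusted p = 0.0373), the only call in that list over all genes and adjusted over the list alone. The call was lost in 8 of 10 fits with a heart left out, all but those without control replicate 1 or S1Pless replicate 4 (adjusted p up to 0.109, without control replicate 4), and with library totals alone (adjusted p = 0.125). Camera called both lists lower (adjusted p = 2.83e-09 and 8.70e-09), with an adjusted p = 0.421 and 0.334 with an estimated correlation. Mitochondrially encoded transcripts, with a median log2 fold change of -0.27 over 9 genes and no call, took 26.9 ± 3.85% of the counts in controls and 24.7 ± 2.18% in S1Pless hearts (exact permutation p = 0.310). Camera gave this list an adjusted p of 0.00411, and an adjusted p = 0.419 with an estimated correlation; without control replicate 1 it did not pass (adjusted p = 0.0532). In 20 genes of glycolysis the median was -0.19 (camera adjusted p = 0.00191, adjusted p = 0.334 with an estimated correlation). Its only called member, over all genes and adjusted over the list alone, the glycolytic activator Pfkfb3, rose 1.57-fold (adjusted p = 0.0215). Its call was lost without control replicates 2 to 4 or S1Pless replicate 5 (adjusted p up to 0.0603, without control replicate 3). Of 16 hypoxia-response genes, with a median of -0.12, Egln3 was the only called one, with 2 lower when adjusted over the list alone (camera adjusted p = 0.0134, adjusted p = 0.334 with an estimated correlation). It lost its call without control replicate 2, 3 or 5 or S1Pless replicate 1 or 2 (adjusted p up to 0.0654, without control replicate 5). The hypoxia list did not pass with the haemoglobin share as a covariate (camera adjusted p = 0.0841).

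Contractile, calcium handling and channel genes also had negative medians with TMM factors, whose choice against library totals alone moves log2 fold changes by a median of 0.136. The 21 sarcomere genes had a median log2 fold change of -0.16 with none past the threshold, the 18 calcium handling genes one of -0.17 and the 21 ion channel and connexin genes one of -0.24. Kcnj3, a subunit of the acetylcholine-activated potassium channel, fell 1.38-fold (edgeR adjusted p = 0.0314), and Itpr2, an intracellular calcium release channel, rose 1.30-fold (adjusted p = 0.0252). Adjusted over the list alone, 2 channel genes were lower, 1 calcium handling gene was higher and no sarcomere gene passed. Kcnj3 lost its call without control replicates 3 to 5 or S1Pless replicate 1, 2, 4 or 5 (adjusted p up to 0.0724, without control replicate 4) or with library totals alone (adjusted p = 0.0708), and Itpr2 without control replicates 2 to 4 or S1Pless replicate 5 (adjusted p up to 0.0755, without S1Pless replicate 5). Camera called the sarcomere, calcium handling and channel lists lower (adjusted p = 0.00411, 0.0220 and 0.000327), with an adjusted p = 0.334, 0.419 and 0.334 with an estimated correlation. The calcium handling list did not pass without control replicate 5 (adjusted p = 0.113) or S1Pless replicate 1 (adjusted p = 0.0687), nor with the haemoglobin share as a covariate (adjusted p = 0.0841).

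None of the classical transcripts of cardiac stress passed the test, and Nppa, Myh7 and Acta1 varied widely between hearts. Nppa, which encodes atrial natriuretic peptide, had 152 ± 103 CPM in controls and 186 ± 109 CPM in S1Pless hearts, a log2 fold change of 0.29 ± 0.62 (edgeR adjusted p = 0.832). Nppb, with 117 ± 22.3 and 165 ± 81.1 CPM, had a log2 fold change of 0.49 ± 0.31 (adjusted p = 0.401) and Myh7, the beta myosin heavy chain, one of 0.38 ± 0.45 (adjusted p = 0.682). Acta1 had one of 0.30 ± 0.49 (adjusted p = 0.778) and Myh6, the alpha myosin heavy chain, with 19530 ± 1781 and 17399 ± 2652 CPM, one of -0.17 ± 0.12 (adjusted p = 0.487). Without S1Pless replicate 2 the values of Nppa and Acta1 were -0.02 and -0.04. Of 13 tested members of the list, Uchl1, a deubiquitinating enzyme better known from neurons, was the only called one, over all genes and adjusted over the list alone (1.44-fold, adjusted p = 0.0498). With a heart left out its call was kept only without control replicate 5 or S1Pless replicate 2 (adjusted p up to 0.125, without control replicate 4). The call was also lost with RLE factors, no filter, the title series covariate or without haemoglobin and mitochondrial genes (adjusted p of 0.0524 to 0.0686). Camera gave the list an adjusted p of 0.237, and 0.0176 with the haemoglobin share as a covariate (adjusted p = 0.648 with an estimated correlation and no covariate).

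**Figure D3:**
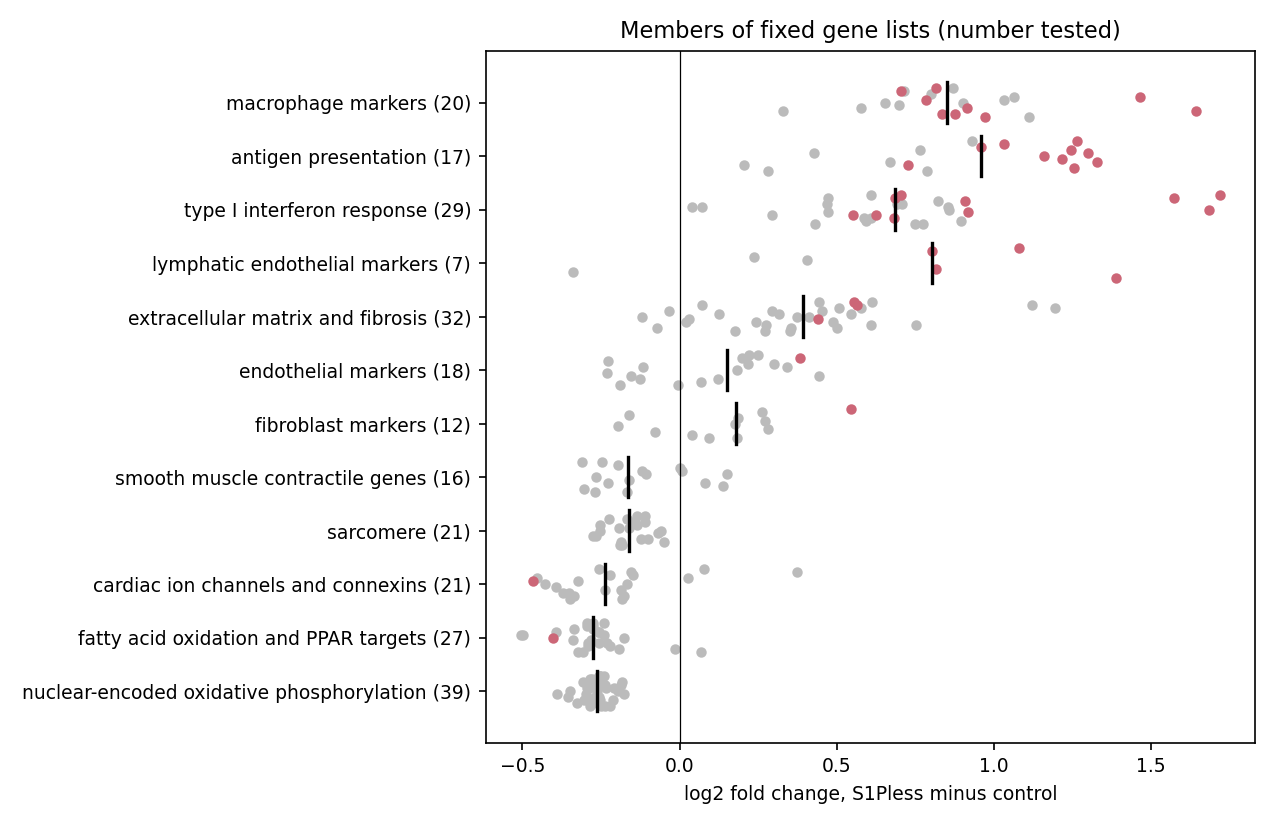
Log2 fold change (S1Pless minus control) of each tested member of 12 of the gene lists; each point is 1 gene, pink where edgeR's adjusted p was below 0.05 and grey otherwise, the vertical bar is the list's median and the number tested is in brackets. Macrophage, antigen presentation and interferon genes lie to the right of 0 with medians of 0.85, 0.96 and 0.69, and oxidative phosphorylation genes lie in a narrow band around -0.26.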

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

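The tests of S1Pless replicate 5 and of the share of heart muscle RNA, and the count over other groupings of the hearts, were chosen only after the results were seen, as was the haemoglobin covariate, for which the bounds were written before its result. A heart was singled out where its gap to the nearest of the other 4 hearts of its group exceeded 0.71 of the group's range (Dixon's 95% critical value). This was examined in 238 groups of 5 values, over 70 genes, 43 gene list scores and 6 library measures, and it singled out 24, where chance gives 11.9. Of the 24, 9 fell on S1Pless replicate 5, 5 on control replicate 1 and 4 on S1Pless replicate 3, and none on a library measure.

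S1Pless replicate 5 stood above the other S1Pless hearts in macrophage and matrix genes. Its macrophage marker score was 5.3814 (mean log2 CPM) against 4.31 to 4.57 in the others, and Csf1r had 126.901 CPM against 56.4 to 71.5. Adgre4 had 6.115 CPM against 2.00 to 2.96, F2rl3 3.461 CPM against 0.929 to 1.6 and Igsf23 3.887 CPM against 0.858 to 1.45. The score of extracellular matrix genes was 5.8234 against 5.03 to 5.18, with Col6a1 at 135.197 CPM against 92.6 to 103. Its scores for platelet markers, at 2.2301 against 0.961 to 1.31, and for genes of S1P synthesis, breakdown and transport, at 4.6741 against 4.44 to 4.48, were also the highest of the group.

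Macrophage, antigen presentation and interferon genes, 66 tested members of which all 66 had positive log2 fold changes with a median of 0.786 (median SE 0.221), were higher in S1Pless hearts by camera with its preset correlation, while each list had an adjusted p = 0.334 with an estimated correlation. The tables argue against S1Pless replicate 5 as the whole cause, since without it the median was 0.631 (mean score 0.642 ± 0.173, SE, adjusted p of 0.181 to 0.436 with an estimated correlation). Replicate 5 was the highest heart only in the macrophage score. S1Pless replicate 1 had the highest interferon and antigen presentation scores, 4.31 and 6.46, against 4.04 and 6.17 in replicate 5. The median of these genes without S1Pless replicate 1 was not computed. For the macrophage genes alone they also argue against a smaller share of heart muscle RNA as the whole cause. The macrophage score rose by 0.760 more than the mean of the endothelial, fibroblast, smooth muscle and pericyte scores (exact permutation p = 0.00794), which differed by 0.0953, 0.141, -0.10 and 0.119. The macrophage list was chosen because it was higher, so this p is no independent support. Antigen presentation and interferon scores were not compared in this way. With the haemoglobin share as a covariate the median was 0.687 (mean score 0.651 ± 0.235, SE, adjusted p of 0.414 to 0.539 with an estimated correlation), although 20 genes in all passed in place of 483, a fall whose cause was not tested. The haemoglobin share alone thus did not account for the higher values. Whether leukocytes in retained blood contribute stays open, since haemoglobin transcripts, whose counts are uncertain here, do not count these cells. With the block for neighbouring title numbers the median was 0.735 (median SE 0.272, adjusted p of 0.433 to 0.437 with an estimated correlation). Loss of S1P from the blood, loss of the kinases within cells of the heart and the recombinase itself stay open, since no sample separates them. Library order stays open too, since the column names number all controls before all S1Pless hearts. Litter does as well: the controls are called littermates, but the litter of each animal is not given in the sources used here. As a hypothesis, more monocytes, macrophages or interferon signalling may be present in S1Pless hearts, which cell counts in sections could test.

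Control replicate 1 stood apart in other genes. It had 156.354 CPM of S1pr1 against 79.3 to 102 in the other controls, 0.987 CPM of Igsf23 against 8.77 to 11.9 and 23.088 CPM of Med16 against 34.8 to 39.0. Its score of mitochondrially encoded transcripts was 12.0174 against 11.3 to 11.4, and its score of ubiquitin ligases and autophagy genes of muscle atrophy 6.724 against 6.93 to 7.00.

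S1Pless replicate 3 had 0.696 CPM of Rad51ap1 against 1.67 to 1.94 in the other S1Pless hearts and 38.304 CPM of Pdp2 against 19.9 to 24.4. Its score of fatty acid oxidation genes was 8.3262 against 7.58 to 7.71 in the other S1Pless hearts and 7.95 to 8.24 in controls, and that of the unfolded protein response 6.4644 against 6.10 to 6.19. S1Pless replicate 2 had 18.563 CPM of Reln against 10.6 to 12.3, and S1Pless replicate 1 a hypoxia response score of 5.699 against 5.86 to 5.88. Control replicate 2 had 1.183 CPM of Aif1 against 2.08 to 2.29 and 13.975 CPM of Nos2 against 17.3 to 18.6. Control replicate 4 had a smooth muscle score of 4.5104 against 4.93 to 5.10 and a score of immediate early genes of 4.3248 against 3.35 to 3.62.

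The 483 genes past the threshold were set against other groupings of the same hearts. Of 100 drawn groupings into 5 and 5, from 126 possible, 2 gave at least as many genes, the real one included, a share below 0.05. That share could exclude chance only if the hearts were free to be exchanged. The likenesses between hearts given next put this in doubt, so no conclusion about chance is drawn. The groupings ignored the neighbouring title numbers, whose 3 pairs of a control and an S1Pless heart had correlations of 0.112 to 0.248 in their deviations, and with a block for such numbers 22 genes passed. The highest other grouping called 863 genes, and the next called 7. The 863 set control replicates 1 and 3 and S1Pless replicates 1, 2 and 3 against the other 5 hearts, which points to a structure of the samples beside their groups. With that grouping as a covariate, chosen from the same data, 745 genes were higher and 312 lower in S1Pless hearts.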

How the results depend on the processing

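The fits with library totals alone, the haemoglobin share, the blocks, the first residual component or without the library of lowest quality weight in each group were chosen after seeing the data. The totals of 442 higher and 41 lower genes stayed within 1.5 times under RLE and upper-quartile factors, limma-voom, both other filters, removal of haemoglobin and mitochondrial genes and the title series covariate, under which 62, 64, 59, 60, 58, 63 and 55 of the 64 called genes named in the text still passed, some being untested with the filter of 1 CPM. DESeq2 called 753 higher and 266 lower, 1019 in all. Leaving out each heart gave 118 to 504 higher, 8 to 85 lower and 126 to 589 in all. Without the library of lowest quality weight in each group, control replicate 1 and S1Pless replicate 1, 281 were higher and 20 lower, 301 in all. The block of neighbouring numbers left 21 higher and 1 lower, 22 in all, the narrower block 69 and 10, 79 in all, and the haemoglobin share 19 and 1, 20 in all; the first residual component, drawn from the same data, gave 847 and 466, 1313 in all. Library totals alone, which shifted log2 fold changes by a median of 0.136, gave 1420 and 13, 1433 in all. No gene called at first reversed its sign in any of these fits. The lists called, 10 higher and 10 lower, fell to 0 and 0 with an estimated correlation and 0 and 0 in fry, and the higher ones to 6 with the narrower block and to 6 with library totals alone. The 6 with the narrower block include the immediate early genes, called only then and without control replicate 4 (camera adjusted p = 0.0467 and 0.0113). These log2 fold changes, none of them called, reversed: Nppa, with -0.0243 to 0.5818 over the fits without a heart, and Acta1, with -0.0394 to 0.6208, each below 0 without S1Pless replicate 2; S1pr1 at -0.0731, S1pr5 at 0.2777 and Hba-a1 at -0.1373 with the haemoglobin share; and Ppbp at -0.054 with the block and -0.4563 with the narrower one; and Clock at 0.0013 with library totals alone. With the haemoglobin share camera reversed its direction for erythroid markers (adjusted p = 0.0143) and the unfolded protein response (adjusted p = 0.617). Except where fewer hearts were used, the cause was not tested. A tally over all fits covered the 111 genes that the naming rule picks from every tested list, not only those described here. Their values stayed on their side of the threshold 2206 times, fell below it 394 times, passed it anew 45 times and reversed 8 times. Camera's list values did so 966, 43, 18 and 2 times. DESeq2 gave 1162 genes a p but no adjusted p. Depth limits the lowest genes, such as Sphk1 with 8 to 27 reads per library.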

Other observations

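The tests of scaling, of the sarcomere score, of paired title numbers and of NF-kappaB targets were chosen only after the results were seen. Camera with its preset correlation also called 3 further lists of immune and proliferation genes higher, with few or no single calls, and none of these lists passed with an estimated correlation. T cell markers had a median log2 fold change of 0.54 over 7 genes (camera adjusted p = 0.0166, adjusted p = 0.334 with an estimated correlation). None passed over all genes and 3 did when adjusted over the list alone, among them Cd4 (log2 fold change 0.99 ± 0.30, edgeR adjusted p = 0.0860) and Thy1 (0.54 ± 0.15, adjusted p = 0.0656). Without control replicate 3 camera gave the T cell list an adjusted p of 0.0584. With a filter of 1 CPM in 5 libraries it had 0.228. With the block, the narrower block and library totals alone the T cell list had 0.140, 0.0822 and 0.0777 and the neutrophil list 0.0561, 0.244 and 0.0922 as adjusted p. Neutrophil markers had a median of 0.64 over 6 genes (camera adjusted p = 0.0140, adjusted p = 0.334 with an estimated correlation), with a call in Hdc, the histamine-forming enzyme also made by mast cells (1.96-fold, adjusted p = 0.0274), both over all genes and adjusted over the list alone, which was lost without control replicates 2 to 4 or S1Pless replicate 1 or 5 (adjusted p up to 0.0734, without control replicate 3). Cell cycle genes had a median of 0.39 over 18 genes with no call over all genes or over the list alone (camera adjusted p = 0.0220, adjusted p = 0.419 with an estimated correlation), Mki67 having 1.06 ± 0.32 (edgeR adjusted p = 0.0860) and Top2a 1.02 ± 0.32 (adjusted p = 0.0990). That list did not pass without control replicate 2 or S1Pless replicate 1 or 5 (adjusted p of 0.0859, 0.0537 and 0.0920), nor with the filter of 1 CPM, the narrower block, the haemoglobin share or library totals alone (0.0506, 0.0822, 0.285 and 0.108). B cell markers showed Ighd as the only call of 7 (camera adjusted p = 0.955).

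Arterial and shear-responsive endothelial genes had a median log2 fold change of 0.20 over 18 genes with no call over all genes or over the list alone (camera adjusted p = 0.0115, adjusted p = 0.334 with an estimated correlation), and that list did not pass with the narrower block (adjusted p = 0.0822) or the haemoglobin share (adjusted p = 0.162). Wt1, the only tested epicardial marker, rose 1.52-fold (edgeR adjusted p = 0.0241) and lost its call without control replicates 3 to 5 or S1Pless replicate 5 (adjusted p up to 0.0675, without control replicate 3), with either block or with the haemoglobin share (0.0749 to 0.180). The unfolded protein response had a median of -0.24 over 17 genes (camera adjusted p = 0.0220, adjusted p = 0.645 with an estimated correlation), while its only call, Edem1, rose 1.32-fold (adjusted p = 0.0388). That list did not pass without control replicate 2 or S1Pless replicate 2 or 5 (adjusted p of 0.446, 0.0654 and 0.0532), nor with the title series, the first residual component or the haemoglobin share as a covariate (0.0615, 0.0537 and 0.617), and Edem1 not without control replicates 2 to 5 or S1Pless replicate 1, 4 or 5 (adjusted p up to 0.105, without control replicate 4). Heat shock genes had a median of -0.21 over 13 genes with no call (camera adjusted p = 0.0323, adjusted p = 0.334 with an estimated correlation), and that list did not pass without control replicate 2 or 3 or S1Pless replicate 5 (adjusted p of 0.139, 0.0584 and 0.0652), nor with the haemoglobin share (adjusted p = 0.378). The list of thymus and lymph node markers, 3 genes with Ccl21a as the only call, had a camera adjusted p of 0.0437, lost in 6 of 10 fits with a heart left out (adjusted p up to 0.0920, without S1Pless replicate 5), and an adjusted p = 0.334 with an estimated correlation. It was also lost with upper-quartile factors (0.0527), DESeq2 (0.484), no filter (0.418), the block (0.0720), the narrower block (0.131) and library totals alone (0.113). The 23 lists that camera did not call had adjusted p-values from 0.0577 to 0.955.

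Single hearts held extreme values of some genes, chosen after their values were seen. Gapdh had 6.77 CPM in S1Pless replicate 1 and 218 to 579 CPM in the other hearts. Slc15a2 had 0.852 and 0.670 CPM in control replicates 3 and 5 and 16.7 to 41.6 CPM elsewhere. The lymphoid chemokine gene Cxcl13 had 24.7 CPM in S1Pless replicate 5 and at most 2.26 CPM in any other heart.

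Genes of oxidative phosphorylation and fatty acid oxidation, 66 in all, lay lower in S1Pless hearts with a median log2 fold change of -0.264 (adjusted p = 0.421 and 0.334 with an estimated correlation). That they lay lower than other genes is not a matter of scaling. Their mean score less the mean of all tested genes, which no scaling factor moves, differed by -0.350 ± 0.109 (SE, exact permutation p = 0.0159). Both lists were picked because they lay lower, so this p is no independent support. The level itself does depend on scaling: with library totals alone their median was -0.129 and that of all tested genes 0.122. Likeness of hearts with neighbouring title numbers cannot be told apart from a difference between the groups: with a block for these the median was -0.216, below the bound of -0.15 set beforehand by less than the SE of the mean score, which differed by -0.232 ± 0.0975 (adjusted p = 0.433 to 0.529 with an estimated correlation). Nor can a smaller share of heart muscle RNA be told apart from a specific change: the mean score of both lists less the sarcomere score differed by -0.140 ± 0.0840 (SE, exact permutation p = 0.119), too wide a spread to decide. Loss of S1P from the blood, loss of the kinases within cells of the heart, the recombinase, litter and library order stay open as well, since no sample separates them.

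The hearts were alike in ways beyond their groups, with 29.8% of the variance left after the groups on a single component. Its loadings were highest for erythroid markers and ribosomal protein genes (medians of 1.85 and 1.73 SD) and lowest for cardiac stress genes (-1.56). Some lists described above as differing between the groups also loaded highly, with 1.55 for oxidative phosphorylation, 1.18 for mitochondrially encoded transcripts and 1.13 for interferon genes. Fatty acid oxidation and macrophage genes did not (-0.04 and 0.05). For the 3 pairs of a control and an S1Pless heart with neighbouring title numbers the mean correlation of deviations was 0.199, against 0.00650 over all 60 pairings (one-sided exact permutation p = 0.0667), so a condition shared by such hearts stays open. Transcript length or GC bias cannot be told apart either, as Spearman's rho of the loading across genes, which are not independent replicates, was -0.256 with length and -0.0385 with GC, the former between the bounds of 0.1 and 0.3 set beforehand. No biological explanation was tested.

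Tnfaip3, Relb, Traf1, Nfkbie, Birc3 and Tnf, targets of the inflammatory transcription factor NF-kappaB, were noticed among the higher genes, from 4.99-fold for Tnf to 1.57-fold for Birc3 (edgeR adjusted p from 0.00776 to 0.0192). With a heart left out only Birc3 lost its call, without control replicate 3 or 4 (adjusted p up to 0.0553), but with the block none of the 6 passed (adjusted p of 0.0706 to 0.151), with the narrower block none (0.0520 to 0.154), with the haemoglobin share only Traf1, and Tnf not without the library of lowest quality weight in each group (0.0517). The hypothesis that NF-kappaB targets are higher as a group was tested on the other 22 genes of an added list that are in no fixed list. Their median log2 fold change was 0.28, 19 of 22 lay above 0, and camera gave an unadjusted p = 0.0350 with an estimated correlation. That is weak support, since 4 of the 43 fixed lists had an unadjusted p of 0.0340 to 0.0490 in this test and none passed after adjustment. The p also rose above 0.05 without control replicate 1 or 2 or S1Pless replicate 1 (0.0543, 0.0508 and 0.0507), with the block (0.0654), the narrower block (0.194), the haemoglobin share (0.0807), the first residual component (0.0586), library totals alone (0.149) and without the library of lowest quality weight in each group (0.0828). Cd40 was the only 1 of them past the threshold over all genes (adjusted p = 0.0173), though not with the haemoglobin share (0.123) or without the libraries of lowest quality weight (0.0504), and 7 passed when adjusted over the list alone. As a hypothesis, NF-kappaB activity may be higher in S1Pless hearts, which staining for nuclear RelA or RelB could test. The list overlaps in function with the macrophage genes, so a higher number of immune cells is a candidate explanation too.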
